A study of Oryza sativa with 9 samples.

How the data were processed

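Leaves of WT, OE and OsCOMT mutant rice were sequenced, with 3 libraries per genotype made with an Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited FPKM values per gene for the 9 libraries. The submitters' processing notes name Bowtie 0.12.2, Cuffdiff and the genome build IRGSP-1.0, without saying which step each served. The table holds 37858 genes under their RAP identifiers, of which 30062 were above 0 in at least 1 library. It also holds 1 further per-sample column, which matches no sample of the series and was not used here.

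The deposited FPKM are whole multiples of the value of 1 read, so reads and library totals were recovered from them. All 30062 genes above 0 resolved into whole reads at a relative tolerance of 3e-07. The totals were 11451237, 11727127 and 11244242 reads for WT replicates 1 to 3, 11809530, 10795517 and 11412304 for OE and 10869192, 10674819 and 11122792 for the mutant. Replicates of a genotype differed by more than counting noise in every pair (chi-square per gene 6.51 to 17.7), and all were kept as separate libraries. This does not tell separate plants from repeat preparations of 1 sample. Counting intervals are exact binomial intervals at 95%, and a group with 0 reads was set to a floor of 3 reads over its libraries. Both cover counting error only.

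The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit, contrasts.fit and eBayes with a mean-variance trend. All 9 libraries were in 1 fit with no covariate, and the 3 contrasts were OE against WT, mutant against WT and mutant against OE. The 19850 genes with a mean of at least 1 FPKM over all libraries were tested. Tests were two-sided with Benjamini-Hochberg adjustment per contrast, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. In data simulated with 200 changed genes among 19594 tested, the fit for OE against WT recovered 65% of those changed by 1 and 92% of those changed by 2 on the log2 scale. It called 9 unchanged genes. The changed genes were drawn only from those above a minimum of expected WT reads, with noise drawn independently per gene. The rates therefore do not cover lower genes or shifts that many genes of a library share.

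Gene lists were tested with camera at a preset correlation of 0.01, for lists of at least 5 tested genes, with adjustment over the lists of a contrast. The design, the groups, the alternatives and 43 lists were fixed before the data were examined. Most lists rested on gene descriptions, which the table does not give, so only the 8 with identifiers had members, and 4 of these could be tested with camera. Further lists were chosen after the table was seen and before their values were. Which of these further lists are described was chosen after their values were seen. The files do not pair identifiers with gene names. Names paired with identifiers come from general knowledge. A name is printed only where the RefSeq table of assembly ASM3414082v1 holds a gene of that name, or of an alias given for it. That gene had to lie on the same chromosome and within 0.03 of the same relative rank. Some printed names are therefore not those of the matched gene: HSP17.3 was matched through HSP17.4 and PAL1 through ZB8. The check was met by 35 of 47 pairs fixed beforehand and 123 of 175 added pairs. Only 1 identifier matched that table directly, and none of its coordinates were used. Counts for the lists fixed in advance include members whose names are not printed, while the further lists hold only members whose names met this check. A result of the flowering list is not reported here. The named genes are OsCOMT, its 5 neighbours on each side, up to 4 members of smallest adjusted p in each list described and, since the largest changes carry no product names, 2 identifiers that rose and 2 that fell per comparison. CCA1 is named under both the neighbours and the clock list.

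The overlap of the comparisons with WT was set against 50 simulations of 9 unchanged libraries and against independent lists. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, quantile normalization, upper-quartile scaling, a fit of only the 2 groups compared, eBayes without trend, array weights, the replicate number as a block, leaving out each of the 9 libraries, and for lists an estimated correlation and ranks. Limma voom on the recovered reads, cameraPR on the moderated statistic, the overlap of genes of smallest p in the simulations, and leaving out a stretch of chromosome 11, were chosen after seeing the data.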

Results

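The series measured transcripts in rice leaves (Oryza sativa) by RNA sequencing at 85 days after sowing, per the age label. The titles of the WT and OE samples carry a number that differs from this age and is not explained, and the mutant titles follow another pattern without it. Leaves of 3 genotypes were compared, each with 3 replicate libraries, which makes 9 libraries in all. WT is the wild type, OE overexpressed OsCOMT, and the mutant carried a mutation of OsCOMT whose type the labels do not give. OsCOMT encodes a caffeic acid O-methyltransferase, an enzyme of lignin synthesis that also acts at the last step of melatonin synthesis. The series title ties the gene to leaf senescence, the vasculature and grain yield, and the comparisons ask how the leaf transcriptome differs when it is raised or mutated. The deposited values were FPKM, reads scaled to gene length and library total. They resolve into whole reads, with totals of 10674819 to 11809530 reads per library. The labels do not say whether replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical. The labels also do not give the hour at which leaves were taken.

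OsCOMT (Os08g0157500, chromosome 8) was at 259, 237 and 228 FPKM in the WT libraries, at 1945, 3162 and 2823 FPKM in the OE libraries and at 226, 398 and 458 FPKM in the mutant libraries. The mean was 241 ± 15.8 FPKM in WT (SD, n = 3) and 2643 ± 628 FPKM in OE (SD, n = 3), a log2 fold change of 3.42 (SE 0.27, limma adjusted p = 0.00043). In the mutant the mean was 361 ± 121 FPKM (SD, n = 3). Its log2 fold change against WT was 0.52 (SE 0.27, limma adjusted p = 0.15), which does not pass the threshold. Without mutant replicate 1 it was 0.82 with an adjusted p of 0.015. The level was above that of WT in 3 of 3 OE libraries, as their label says. It does not check the label of the mutant libraries, since a mutation can leave the transcript in place. Of the 5 annotated genes on each side of OsCOMT, 6 were high enough to test. CCA1 (Os08g0157600), which encodes a transcription factor of the circadian clock, was at 8.37 ± 1.28 FPKM in WT, 7.94 ± 0.77 FPKM in OE and 399 ± 58.1 FPKM in the mutant (SD, n = 3). Its log2 fold change in the mutant against WT was 5.42 (SE 0.14, limma adjusted p = 8.8e-08). Os08g0157400 rose by 0.68 and Os08g0157100 by 0.28 on the log2 scale in the mutant (adjusted p = 0.0082 and 0.032), and the other 3 tested neighbours did not pass in either comparison with WT.

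**Figure D1:**
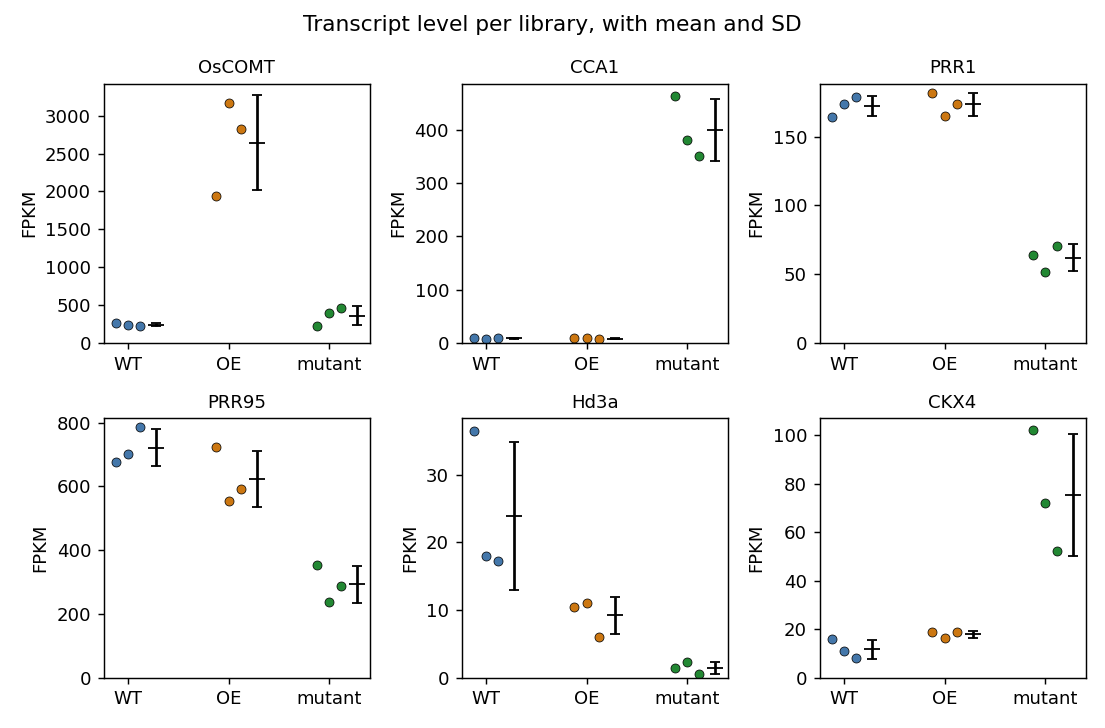
FPKM of 6 genes in each of the 9 libraries (points, 3 per genotype), with the mean and SD of each genotype beside them. OsCOMT was highest in the 3 OE libraries, and CCA1 was at 352 FPKM or more in the 3 mutant libraries and at 9.2 FPKM or less in the other 6.

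Of 19850 genes tested, 46 passed the threshold in OE against WT, 34 higher and 12 lower, and 35 of them also changed by at least 1 on the log2 scale (27 higher, 8 lower). At an unadjusted p under 0.05 there were 2007 genes, and groups did not overlap for 16.4% of the genes, where chance gives 10%. No product names are paired with the IDs of the strongest changes. Os11g0206000 had 2 reads over the 3 WT libraries and 117 ± 12.2 FPKM in OE (SD, n = 3), 3560-fold more with a 95% counting interval of 984 to 29400. Os04g0397800 had 0 reads in WT and 17.1 ± 5.82 FPKM in OE, at least 294-fold higher. Os11g0214900 went from 128 ± 23.4 FPKM to 0 reads, at least 1030-fold lower in OE, and Os09g0120900 fell by 3.09 on the log2 scale (adjusted p = 0.00056). Of the 46 calls, 21 lay among 85 tested genes between Os11g0197600 and Os11g0227100 on chromosome 11, 16 higher and 5 lower. Outside that stretch 25 of 19765 tested genes were called. The ends of the stretch were chosen from these calls, so the difference in share is not a test.

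**Figure D2:**
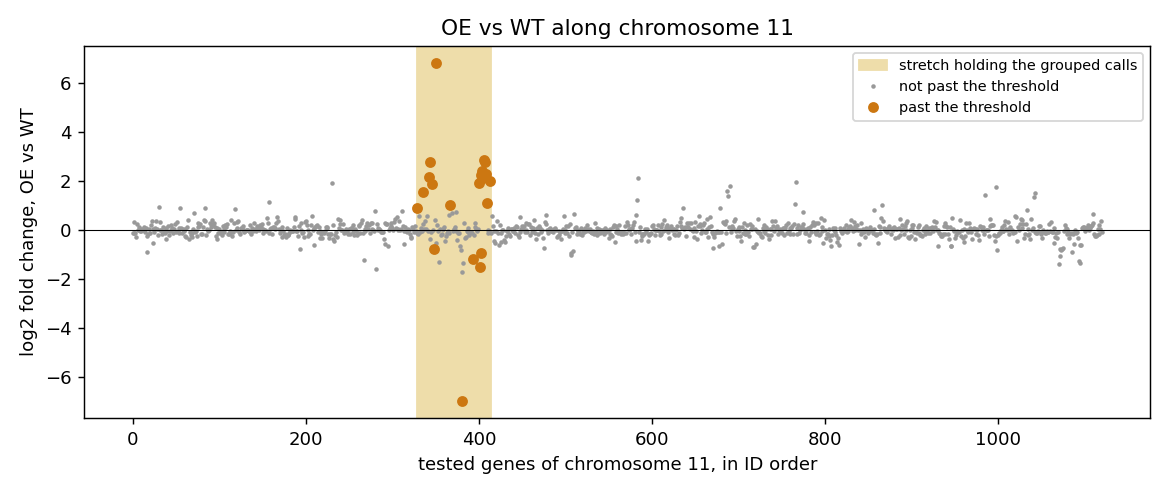
Log2 fold change of OE against WT for each tested gene of chromosome 11, in the order of the IDs, with genes past the threshold as large points. The shaded stretch, whose ends were chosen from the calls, holds 21 calls among 85 tested genes.

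Among the lists fixed in advance, the cytokinin list was higher in OE by camera (median log2 fold change 0.56, adjusted p = 7.8e-05), and this held with an estimated correlation (adjusted p = 0.042). None of the 9 tested members passed over all genes with limma (6 had an unadjusted p under 0.05, and 0 passed with voom), and 4 rose when adjusted over the list alone. The response regulators RR6, RR4 and RR1 had log2 fold changes of 1.27 (SE 0.42), 0.83 (SE 0.27) and 0.40 (SE 0.14), and the cytokinin oxidase CKX3 0.56 (SE 0.18). The circadian clock list was lower by camera (adjusted p = 0.029), with 0 of 11 members past over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or with voom, and its call was lost with an estimated correlation (adjusted p = 0.32). It was also lost without WT replicate 3, OE replicate 2 or OE replicate 3 (adjusted p = 0.13, 0.14 and 0.093), and with cameraPR on the moderated statistic (adjusted p = 0.056). PRR73, PRR95, GI and ELF3-1 had log2 fold changes of -0.22, -0.21, -0.19 and -0.16. The melatonin pathway list, which contains OsCOMT itself, was higher (adjusted p = 0.029) with OsCOMT as its only member past the threshold, also when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.13), on ranks (adjusted p = 0.19) and without WT replicate 2 (adjusted p = 0.081). The number of lists fixed in advance that were higher in OE also fell from 2 to 1 without OE replicate 2 or 3, or mutant replicate 2 or 3. It was 1 as well with a pseudocount of 0.1, a filter at a mean of 5 FPKM or voom. Whether a list lost its call there or had too few tested members is not given here. T5H, ASMT1 and SNAT1, which act upstream in melatonin synthesis or share its last step, had log2 fold changes of 0.52 (SE 0.41), -0.36 (SE 0.33) and 0.03 (SE 0.13). Of the senescence list 0 of 8 members passed with limma either way, at an unadjusted p under 0.05 or with voom, and the list did not pass (camera adjusted p = 0.061). It was lower on ranks (adjusted p = 0.029), and without WT replicate 1 (adjusted p = 0.00031), OE replicate 3 (0.043), mutant replicate 1 (0.038) or mutant replicate 3 (0.041). NAC2, NOL, RCCR1 and NYC1 had log2 fold changes of -0.25, -0.22, -0.19 and -0.11. The flowering gene Hd3a, which encodes a mobile signal that induces flowering, had a log2 fold change of -1.25 (SE 0.36). It did not pass over all genes (adjusted p = 0.27). DTH8 had a log2 fold change of -0.21.

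The number of OE calls was 27 without WT replicate 1, 71 without OE replicate 1 and 29 with a filter at a mean of 5 FPKM. With the genes of the chromosome 11 stretch left out of the test, 14 passed. OE replicate 1 stood apart from the other OE libraries on the second principal component, at -2.5 against 31.8 and 29, with the WT libraries at -22.7 to -17.4.

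The mutant differed from WT in a large part of the transcriptome. Of 19850 genes, 8333 passed the threshold (42%), 3883 higher and 4450 lower, and 2979 also changed by at least 1 on the log2 scale (1386 higher, 1593 lower). Groups did not overlap for 55.4% of the genes, where chance gives 10%. The first principal component held 72.2% of the variance and set the 3 mutant libraries apart from the other 6. Os12g0189300 rose by 5.98 and Os06g0661200 by 5.97 on the log2 scale, while Os09g0343200 fell by 6.66 and Os01g0922700 fell by 6.65.

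**Figure D3:**
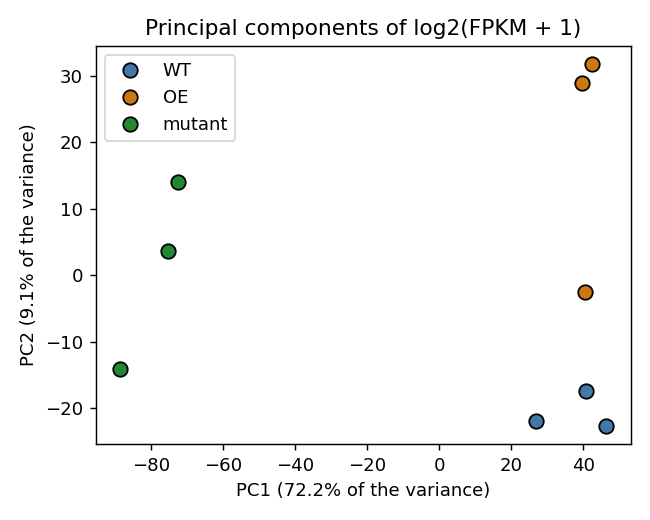
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1), which hold 72.2% and 9.1% of the variance. The 3 mutant libraries lie at -72.6 or below on the first, and the WT and OE libraries at 26.9 or above.

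Clock genes moved in both directions in the mutant. Of 11 tested members of the clock list, 1 rose and 6 fell, over all genes and adjusted over the list alone. Beside the rise of CCA1, the evening-phased gene PRR1 went from 172 ± 7.15 to 61.9 ± 9.70 FPKM (SD, n = 3), a log2 fold change of -1.47 (SE 0.11, adjusted p = 1.4e-05). PRR95 fell by 1.32 (SE 0.16) and GI by 0.46 (SE 0.13, adjusted p = 0.016) on the log2 scale. GI missed the threshold without WT replicate 1 (adjusted p = 0.052) and without mutant replicate 2 (adjusted p = 0.061). The list was lower by camera (adjusted p = 0.017), which was lost with an estimated correlation (adjusted p = 0.33). It was also lower in OE against the same WT libraries, so the results are not independent, and it did not pass by camera in the mutant against OE (adjusted p = 0.12).

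The flowering genes Hd3a and DTH8 fell in the mutant. Hd3a went from 23.9 ± 10.9 FPKM in WT to 1.42 ± 0.90 FPKM (SD, n = 3), a log2 fold change of -3.35 (SE 0.36, adjusted p = 8.9e-05). DTH8, a flowering repressor, fell by 1.32 (SE 0.21, adjusted p = 0.00082). The flowering list had too few tested members for camera.

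Of 9 tested cytokinin genes, 6 rose, 0 fell and 3 did not pass in the mutant, and 7 rose when adjusted over the list alone. The cytokinin oxidase gene CKX4 went from 11.7 ± 3.95 to 75.5 ± 25.2 FPKM and CKX11 from 8.28 ± 5.24 to 41.64 ± 8.998 FPKM (SD, n = 3), log2 fold changes of 2.58 (SE 0.26) and 2.36 (SE 0.40). CKX2 had 4 reads over the WT libraries and 402 over the mutant libraries, 106-fold more with a 95% counting interval of 41 to 391. On the log2(FPKM + 1) scale, which understates this change, its log2 fold change was 2.38 (SE 0.47). RR1, a response regulator induced by the hormone, rose by 1.01 (SE 0.14). The list was higher by camera (adjusted p = 0.0057), which was lost with an estimated correlation (adjusted p = 0.14). It was also higher in OE against the same WT libraries, so the results are not independent, and it did not pass by camera in the mutant against OE (adjusted p = 0.14).

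Of 8 tested genes of chlorophyll breakdown and senescence, 4 rose and 1 fell in the mutant, over all genes and adjusted over the list alone. SGR, which encodes the magnesium dechelatase that starts chlorophyll loss, went from 66.9 ± 46.2 to 264 ± 50.9 FPKM (SD, n = 3), a log2 fold change of 2.22 (SE 0.51, adjusted p = 0.0069). NOL rose by 0.59 (SE 0.18) whereas NYC1, its partner in chlorophyll b reduction, fell by 0.95 (SE 0.16). NAC2 did not pass (log2 fold change 0.46, adjusted p = 0.26). The list as a whole did not pass (camera adjusted p = 0.12). In the melatonin pathway list 1 of 5 tested members rose, over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.14). That member was ASMT1, an acetylserotonin methyltransferase gene, at 2.51 ± 1.09 FPKM in WT and 8.77 ± 3.95 FPKM in the mutant (log2 fold change 1.44, SE 0.33, adjusted p = 0.0063). T5H and SNAT1 had log2 fold changes of 0.54 (SE 0.41) and 0.05 (SE 0.13). The 3 cellulose synthase genes of the secondary wall list lay below the level tested. SUT1, a sucrose transporter of phloem loading and the only member of the phloem list fixed in advance, had a log2 fold change of -0.52 in OE (adjusted p = 0.32) and rose by 1.27 in the mutant (SE 0.16, adjusted p = 0.00027).

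**Figure D4:**
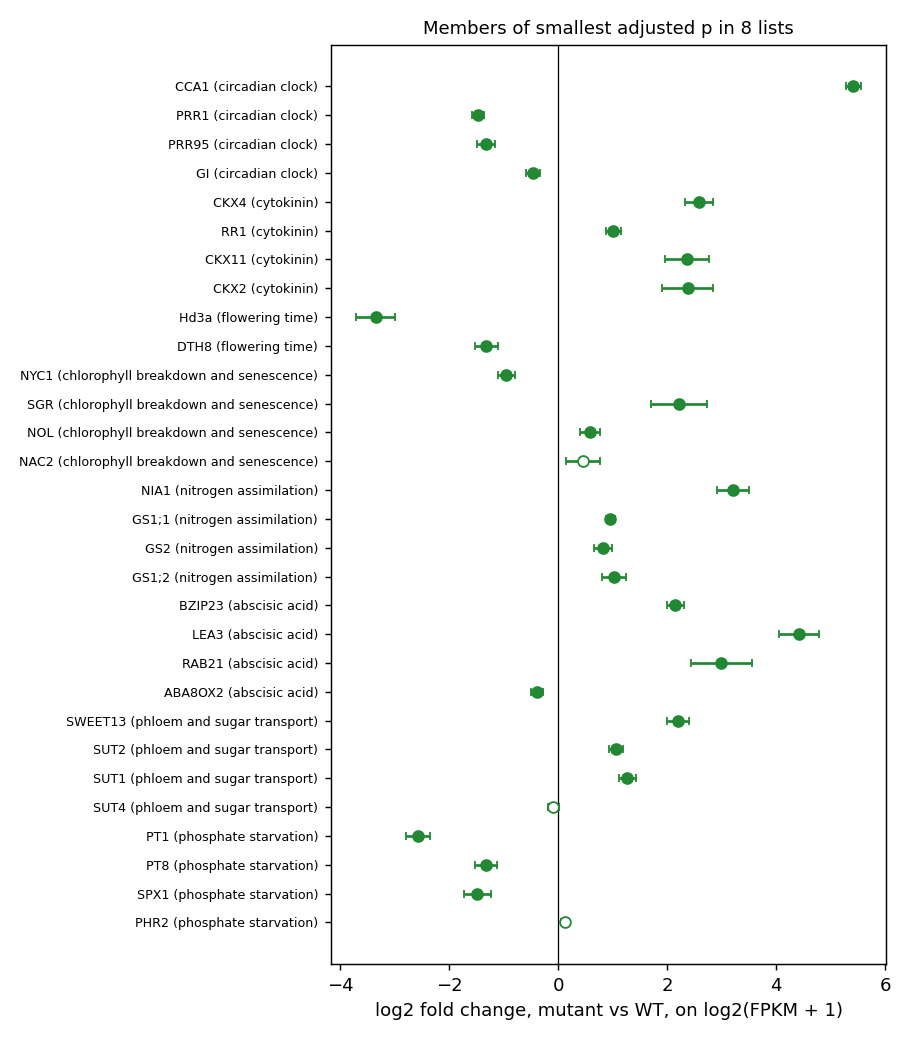
Log2 fold change of the mutant against WT (points) with its standard error (bars) for up to 4 genes of smallest adjusted p in each of 8 lists. Filled points passed the threshold over all genes, and open points did not.

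Between the mutant and OE, 8622 genes passed the threshold, 4067 higher and 4555 lower in the mutant, of which 3117 changed by at least 1 on the log2 scale. Os06g0661200 and Os12g0189300 were higher by 6.17 and 5.73 on the log2 scale, while Os11g0206000 fell by 6.88 and Os01g0922700 fell by 6.46. OsCOMT was lower in the mutant than in OE, with a log2 fold change of -2.90 (SE 0.27, adjusted p = 3.3e-05). CCA1 differed by 5.48 (SE 0.14), PRR1 by -1.48 and PRR95 by -1.10, and GI did not pass (-0.27, adjusted p = 0.11). Hd3a and DTH8 had log2 fold changes of -2.10 and -1.11, each past the threshold. CKX11, CKX4 and RR1 were higher by 2.63, 1.97 and 0.61, and CKX3 was lower (-0.74, adjusted p = 0.0089). None of the 4 lists fixed in advance that could be tested passed in this comparison with camera (lowest adjusted p = 0.1, for the senescence list, which was higher in the mutant without WT replicate 1 or mutant replicate 3, at adjusted p = 0.034 and 0.048). Of the 12 lists chosen later, the floral, nitrogen assimilation and phloem lists were higher in the mutant (adjusted p = 0.012, 0.012 and 0.016), and each call was lost with an estimated correlation (adjusted p = 0.17). For the phloem list that estimate was -0.2, below the preset 0.01, so members varying together do not account for its loss. The abscisic acid list did not pass (adjusted p = 0.063, and 0.12 on ranks), but was higher with cameraPR on the moderated statistic (adjusted p = 0.018) and without mutant replicate 1, 2 or 3 (0.041, 0.028 and 0.031). The heat shock list was higher without mutant replicate 3 (adjusted p = 0.03 against 0.2), and the pathogenesis-related list was lower without OE replicate 1 (adjusted p = 0.023 against 0.15).

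Of the 46 genes called in OE and the 8333 called in the mutant against the same WT libraries, 23 were called in both, 17 in the same and 6 in opposite directions. Independent lists of these sizes give 9.3 and 10. Simulated libraries with no effect gave 0, which is no measure of the overlap because they had at most 1 call per comparison. In them the 46 and 8333 genes of smallest p shared 39.1 on average (33 to 43), 37.9 in the same direction. Both rankings there follow noise alone, whereas in the real libraries 42% of the genes were called in the mutant. The simulations therefore do not show how many of the 23 the shared WT libraries could give. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.14 and a covariance of 0.036, against 0.49 and 0.018 in the simulations. The 3 WT libraries are too few to split, so part of the excess over independent lists may come from the shared controls. With the chromosome 11 stretch left out, 6 genes were called in both, 4 in the same and 2 in opposite directions, where independent lists give 2.9 and 3.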

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

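The voom fit, cameraPR on the moderated statistic and the fits without the chromosome 11 stretch were chosen after seeing the data. The counts for the mutant moved least, from 6523 to 9003 genes against WT (8333 as reported) and from 6680 to 9086 against OE (8622 as reported) over all alternatives, within 1.5 times throughout. Voom on the recovered reads called 8236 genes against WT and shared 8046 of the 8333 calls, with the same direction. For OE against WT the count of 46 fell to 29 with a filter at a mean of 5 FPKM, where fewer genes were tested. It ranged from 27 to 71 when single libraries were left out, lowest without WT replicate 1 and highest without OE replicate 1, and the cause was not tested. It was 14 without the genes of the chromosome 11 stretch, which takes 21 calls away and makes the adjustment stricter for the rest. Voom gave 36, all shared. The overlap of 23 ranged from 11 to 38 when single libraries were left out (14 without WT replicate 2 and 15 without OE replicate 3), lowest without WT replicate 1 and highest without OE replicate 1, and was 6 without the stretch. OsCOMT kept its direction and its side of the threshold under every alternative in OE against WT and in the mutant against OE. In the mutant against WT its log2 fold change ranged from 0.31 to 0.82 when single libraries were left out and passed only without mutant replicate 1 (0.82), and the cause was not tested.

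The counts of lists here refer to those fixed in advance that had enough tested genes for camera, 4 in the reported fit. Those past the threshold went, with an estimated correlation, from 3 to 1 in OE against WT, the cytokinin list remaining, and from 2 to 0 in the mutant against WT. Leaving out single libraries gave 1 to 4 lists in OE against WT, with 1 without OE replicate 2. In the mutant against OE, where 0 of these passed, 2 passed with no filter, 1 with only the 2 groups in the fit, and 0 to 1 when single libraries were left out. The causes were not tested. No pairing of the samples by replicate number was seen. Deviations of same-numbered libraries had correlations of -0.068 to 0.211, and 1 of 9 libraries correlated best with its own number in both other genotypes, which unrelated numbers can also give. With the replicate block the counts were 38, 8318 and 8543 genes in OE against WT, mutant against WT and mutant against OE. The block gave an overlap of 19, lists past the threshold of 3, 2 and 0 in the same order, and OsCOMT log2 fold changes of 3.42, 0.52 and -2.90.

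Of the single genes named, 7 values in 4 results changed sign, all in genes that did not pass. When single libraries were left out, SNAT1 ranged from -0.05 to 0.15 in OE and from -0.04 to 0.14 in the mutant, SUT2 in OE from -0.23 to 0.02, and SLR1 in the mutant from -0.02 to 0.14. For the mutant against WT, 52 of 1482 values lost the threshold and 26 gained it, and in the mutant against OE 278 of 278 kept their call. At 10674819 to 11809530 reads per library, genes below a mean of 1 FPKM were not tested in the reported fit. With no filter, those above 0 were tested too. Then 8792 genes passed in the mutant against WT, with 7644 of the 8333 reported calls among them. In the mutant against OE 9086 passed, with 7916 of the 8622 reported calls. How many of these calls lay below 1 FPKM was not counted.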

Other observations

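The gene lists in these first paragraphs were chosen after the table was seen and before their values were, while cameraPR on the moderated statistic, the window test on chromosome 11, the library within the mutant depths and the setting of the GI bound against its SE were chosen after the results were seen. Nitrogen assimilation genes rose in the mutant, 5 of 5 tested members of the list. A further 4 tested genes were left out of it because their names did not meet the check against the RefSeq table, and of these 2 rose and 2 did not pass. NIA1, a nitrate reductase gene, went from 5.21 ± 1.14 to 55.8 ± 3.43 FPKM (SD, n = 3), and the glutamine synthetase genes GS1;1, GS1;2 and GS2 rose by 0.96, 1.02 and 0.82 on the log2 scale. The list passed camera (adjusted p = 0.0096), which was lost with an estimated correlation (adjusted p = 0.27). Of 5 tested abscisic acid genes 3 rose and 1 fell, and the list did not pass (adjusted p = 0.099, and 0.16 on ranks). It passed without mutant replicate 3 (adjusted p = 0.047) and with cameraPR on the moderated statistic (adjusted p = 0.023). The name check left out 1 further tested gene of this list, which fell. The dehydration-induced genes LEA3 and RAB21 had 0 reads in the WT libraries and were at least 340-fold and at least 79-fold higher in the mutant, where RAB21 was at 9.82 ± 9.78 FPKM (SD, n = 3). BZIP23, a regulator of abscisic acid responses, rose by 2.15 and ABA8OX2, a catabolic gene, fell by 0.39. Sugar transporters SWEET13, SUT1 and SUT2 rose by 2.2, 1.27 and 1.06 in the mutant, 3 of 5 tested members of the wider phloem list (adjusted p = 0.099, 0.16 on ranks and 0.045 with cameraPR on the moderated statistic), and SUT4 had a log2 fold change of -0.09. In OE the same list was lower (adjusted p = 0.005, but adjusted p = 0.18 with an estimated correlation and 0.054 on ranks), with 0 members past over all genes with limma or voom and 3 at an unadjusted p under 0.05. SWEET13, SWEET14, SUT1 and SUT2 had log2 fold changes of -0.73, -0.58, -0.52 and -0.14 there. The estimated correlation of this list was -0.2, below the preset 0.01, so members varying together do not account for the loss with that setting.

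Of 4 tested phosphate starvation genes 3 fell in the mutant. The phosphate transporter genes PT1 and PT8 fell by 2.57 and 1.33 and SPX1 fell by 1.48, while PHR2 had a log2 fold change of 0.13. RCA, the activator of rubisco, went from 192 ± 7.06 to 2502 ± 486 FPKM (SD, n = 3), and PETE rose by 0.63. CAB2R and CAB1R did not pass (-1.31 and 0.30). In chlorophyll synthesis CHLH and DVR rose by 1.30 and 0.84 and PORA and CHLI fell by 4.44 and 0.43. CATB fell by 0.93 while APX2, SODCC1 and APX1 rose by 0.98, 0.93 and 0.45. The heat shock genes HSP17.3, HSFA2A and HSP101 rose by 3.56, 2.30 and 1.39, and BIP1 did not pass (-0.23). HSFA2A missed the threshold with voom (adjusted p = 0.085). MADS16, MADS1 and MADS18 rose by 1.58, 0.94 and 0.86, and MADS14 did not pass (0.08). LOX7 fell by 3.35, JAZ11 rose by 1.71, and JAZ12 and OPR1 did not pass (1.67 and 0.80). NPR1 and WRKY24 fell by 1.42 and 1.24, CHT1 rose by 1.34, and WRKY71 did not pass (-0.56). 4CL2 rose by 2.86, and PAL1, 4CL5 and 4CL4 did not pass (-0.92, -0.51 and -0.32). GA20OX2 and GID1 rose by 1.24 and 0.43, and SLR1 did not pass (0.06). AGPS2 and WX rose by 0.96 and 0.68 and SUS2 fell by 0.43. None of these lists passed camera in the mutant where it had 5 tested genes, but the heat shock and floral lists were higher without mutant replicate 3 (adjusted p = 0.037 and 0.047). Apart from the nitrogen and abscisic acid lists, the name check left 30 tested genes out of the lists described here, of which 10 rose, 5 fell and 15 did not pass. In OE the floral and jasmonate lists passed (both adjusted p = 0.0039, and adjusted p = 0.18 and 0.53 with an estimated correlation), with 0 members past over all genes with limma or voom and 3 in each at an unadjusted p under 0.05. MADS15, MADS18, MADS16 and MADS14 had log2 fold changes of -1.34, -0.45, -0.37 and -0.28, and JAZ11, JAZ12, LOX7 and AOC 1.83, 1.57, 1.05 and 0.18. Without OE replicate 3 the chlorophyll synthesis and light reaction lists were higher in OE (adjusted p = 0.00031 and 0.0093, against 0.38 and 0.42). The pathogenesis-related list was higher without OE replicate 1 or WT replicate 1 (adjusted p = 0.0052 and 0.028, against 0.23), and the phenylpropanoid list lower without OE replicate 2 (adjusted p = 0.044 against 0.38). The jasmonate call was lost without OE replicate 3 (adjusted p = 0.12). JAZ12 was at 2.2, 6.62 and 24.85 FPKM in OE replicates 1 to 3 and at 1.32 to 3.05 FPKM in WT, and JAZ11 at 3.05, 11.1 and 20.52 FPKM in OE and 1.18 to 3 FPKM in WT. OE replicate 1 stood apart from the other OE libraries on the second principal component (-2.5 against 31.8 and 29).

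CCA1 and 8333 genes in all differed between the mutant and WT, and 3 explanations were weighed beside an effect of the mutation itself, which stays open and untested. Quantile normalization kept 93.1% of the calls with their direction. The depths of mutant (at most 11122792 reads) and WT (at least 11244242 reads) did not overlap, so the prediction's condition for excluding depth or composition was not met. OE replicate 2 lay within the mutant depths at 10795517 reads with 8.4 FPKM of CCA1, against at least 351.9 FPKM in the mutant. This argues against depth for CCA1 only, rests on 1 library, and does not cover the other genes or the composition of the mutant libraries. A disturbance of the whole neighbourhood of OsCOMT is argued against by its 5 other tested neighbours, whose median absolute log2 fold change of 0.24 was at the 34.2 percentile of all such windows. A median does not cover single genes. Os08g0157400, the ID next to OsCOMT, rose by 0.68 and Os08g0157100 by 0.28 (limma adjusted p = 0.0082 and 0.032), where 42% of all tested genes passed. An effect on CCA1 or on single neighbours therefore stays open. Another hour of sampling predicted falls of at least 1 in both PRR1 and GI: PRR1 fell by 1.47 and GI, at -0.46, did not, and GI also passed the bound of -0.5 set beforehand for excluding this, with a 95% interval of -0.74 to -0.17, though by 0.04, less than its SE of 0.13. The labels give no hour for any library and the mutant titles follow another pattern than those of WT and OE, so the hour of sampling, a separate collection and the genotype cannot be told apart, and the genes that follow the clock may differ for any of these reasons.

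Of the 46 calls in OE, 21 lay in 1 stretch of chromosome 11, and 5 of the 6 genes with 0 reads in WT and at least 20 in each OE library lay there too. The fullest window of 60 adjacent tested genes held 14 calls, against at most 5 in 10000 permutations of the calls (p = 1e-04, the smallest they can give). These permutations treat adjacent genes as unrelated, so they do not allow for neighbours that vary together. The 46 genes of smallest p in the mutant put at most 2 in such a window. This argues against such clustering of the most strongly changed genes in the mutant, the 1 comparison checked, and does not cover others. A candidate explanation is that the OE plants carry another version of this segment, from another parent or from a rearrangement. A local effect of the transgene's insertion was not tested and stays open, and the files hold no sequence to decide between them.

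The 6 libraries of each pair of genotypes make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of 10 in each case, gave 46 genes for OE and WT (highest of the others 0), 8333 for the mutant and WT (highest 1) and 8622 for the mutant and OE (highest 0). Every other split mixes the genotypes within its groups, so a difference between them adds to the spread and lowers the count. The gap between the counts therefore adds no support.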
